A study of Mus musculus with 10 samples.

How the data were processed

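CD8+ T cells were isolated from the bone marrow of C57BL/6 mice with a magnetic kit, sorted by flow cytometry and profiled by droplet single-cell RNA sequencing (10x Chromium). The mice were either free of tumour or had received cells of Vk12653, a transplantable mouse multiple myeloma, and treatment with an agonist antibody against CD137 (4-1BB, a costimulatory receptor of activated T cells encoded by Tnfrsf9) or with control IgG began 10 days later. Each sample was 1 library whose label names 5 mice, so a library is a pool and the spread between mice is unknown. The labels list 10 samples, and the deposited table holds cells of 9 of them. The control IgG sample of day 4 has no cells there, so anti-CD137 against control IgG on day 4 was not analysed here. The names of the control cells carry the word PBS where the sample labels say IgG; the labels were followed.

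Per the submitters' processing notes, Cell Ranger 3.0.2 and Seurat 3.0 were used with the mouse build mm10. The authors deposited 1 table with 51902 cells in rows and 13932 genes in columns, whose values are the natural log of 1 plus a whole number. All 723098664 values were checked, and 100% gave a whole number within 1e-06 when the log was undone. The whole numbers added up to between 2672 and 4775 in every cell, so the depth had been equalised between cells and the values are not raw molecule counts. How the authors selected cells and genes is not stated. The raw depth is therefore unknown, and no counting intervals or detection floors are given for genes. The log was undone, and the whole numbers were summed over the cells of a library and divided by the library's sum to give a level in CPM, counts scaled to the same total. Gene positions are from the GENCODE vM21 annotation of the same build and matched 243 of 245 named genes by symbol.

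Cells with at least 200 genes and at most 10% mitochondrial values were kept, which left out 25 cells and kept 51877. They were clustered with scanpy 1.11.5 and leidenalg 0.10.2 on 2000 variable genes, 30 principal components, 15 neighbours and a Leiden resolution of 1, with seed 0. Haemoglobin genes were left out of the clustering. The 14 clusters were named from marker lists, and such a name is followed by "-like" because it rests on transcripts alone. Clusters in which at least 5 of 7 T cell markers were present counted as CD8 T-like. These were then placed in tiers by 8 naive T cell markers, each called present at a level of at least 1 in 3 parts of that in the cluster with the most. Clusters with at least 6 present were called naive-marker-high and those with at most 2 naive-marker-low, while a cluster that the memory markers named formed a memory-like tier of its own. A cluster whose markers pointed to 2 classes was left unnamed. The naming thresholds, the exclusion of haemoglobin genes, the tier limits, the memory-like tier and the rule for unnamed clusters were set after the data had been seen. The tests, the 17 gene lists of T cell programmes, the 10 lists of other cell types and the rule for naming genes were fixed before the data were examined. Naming the largest values where no gene passed was not part of that rule. The tests were planned with day 4 included, as an early day in the late-against-early test. That day dropped out because its control has no cells. Shares of cells carry exact Clopper-Pearson 95% confidence intervals, which cover the sampling of cells only.

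Effects of anti-CD137 across days were tested with limma 3.58.1 in R 4.3.3, the method set in advance for a table without raw counts. The input was log2 of the level in CPM plus 10 for genes with a mean of at least 5 CPM. The model held treatment day as a block and antibody as a term over the 6 libraries of days 1, 11 and 18, and a trend was fitted to the variances. This tests the effect shared by the 3 days. It was run on all CD8 T-like cells and on non-naive CD8 T-like cells, which are those of the memory-like and naive-marker-low tiers. A second model tested whether the effect on days 11 and 18 differed from that on day 1, with 1 residual degree of freedom. The Benjamini-Hochberg threshold was 0.05. Gene lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, and adjusted over the lists of a kind. Camera asks whether a list moves more than other genes, whereas fry asks whether its members move, on balance, one way.

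Comparisons of 1 library with another have no replicates and no test. For them, log2 ratios of the levels in CPM were taken with 10 added to both. A list's median log2 ratio was compared with the central 95% of 10000 random lists matched in 20 bins of expression, which shows whether the list stands out from other genes but says nothing of the spread between mice. Lists with fewer than 3 members at a mean of at least 5 CPM were not scored. Genes were named by rank. In comparisons of single libraries, these were the 10 highest and 10 lowest log2 ratios at 50 CPM or more in either library, without antigen receptor, mitochondrial, ribosomal protein and sex-linked genes, and up to 4 members per list. In tests, they were the members of lists past the threshold with the largest changes, or the largest values where none passed, and the 10 smallest p values of the late-against-early test. Tnfrsf9, Cd8a and Cd3e were named throughout.

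The limma tests were checked on simulated data with 8535 genes in the same layout, with 200 genes changed. The averaged test called 188 of the 200 (94.0%) and 4 unchanged genes. The late-against-early test called 75 of the 200 (37.5%) and 5 unchanged genes, 58 of 66 at a 4-fold change (87.9%), 17 of 67 at a 2-fold change (25.4%) and 0 of 67 at a 1.5-fold change. The simulated genes varied independently, which real genes do not. Their noise was the spread over the 5 libraries up to day 4, 2 of them without antibody. In the averaged run the planted change was the same on every day. An effect that differs between days enters the error of that test, so 94.0% is not its power on these data.

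The alternatives tried were TMM and median-of-ratios scaling, no low-value filter, at least 10 CPM in at least 4 libraries, pseudocounts of 1 and 50 CPM, all deposited cells, stricter cells (at least 500 genes and at most 5% mitochondrial values), equal numbers of cells per library, no block for day, leaving out each day, other clusterings, and subsets of cells. Scrublet marked 37 of 51902 cells as doublets (0.0713%), too few for a run without the marked cells to tell anything. It was run on depth-equalised values, so this does not show that doublets were few. Other tools were Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, scikit-learn 1.9.0 and matplotlib 3.10.9.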

Results

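Transcripts were measured in single bone marrow CD8+ T cells of mice that carried no tumour, carried myeloma, or carried myeloma and received anti-CD137 or control IgG for up to 18 days. The table held 6874 cells of naive mice and 5718 cells of myeloma-bearing mice taken before any antibody. Of treated mice it held 5205 cells given anti-CD137 and 5406 given control IgG on day 1, 5748 given anti-CD137 on day 4, 5156 and 5610 on day 11, and 6813 and 5372 on day 18. The depth-equalised values of a library added up to between 19320639 and 24124594, with medians of 3343 to 3827 per cell, and median genes per cell ran from 1111 in naive mice to 1455 in the anti-CD137 library of day 11. There was 1 library per group, so values of single libraries carry no replicate error. The most abundant gene was Ccl5, a T cell chemokine, in the anti-CD137 libraries of days 11 and 18, the ribosomal gene Rps24 in the control IgG library of day 11, and the nuclear RNA Malat1 in the others.

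Shares of cell classes were compared to ask how the make-up of bone marrow CD8 T cells changed with myeloma and with the agonist. Naive-marker-high cells, which carry Ccr7 and Lef1 transcripts typical of T cells that have not met antigen, made up 96.7% of cells in naive mice and 96.5% in myeloma-bearing mice before treatment. Under control IgG they made up 98.4% on day 1, 89.3% on day 11 (95% confidence interval 88.5 to 90.1) and 79.1% on day 18 (78.0 to 80.2). Under anti-CD137 they made up 97.4% on day 1 and 96.6% on day 4, but 14.8% on day 11 (13.9 to 15.8) and 3.25% on day 18 (2.84 to 3.70). Naive-marker-low cells made up 69.3% on day 11 (68.0 to 70.5) and 89.0% on day 18 (88.2 to 89.7) under anti-CD137, against 1.52% (1.21 to 1.87) and 6.78% (6.12 to 7.48) under control IgG. These are shares of the cells captured, so a loss of naive cells cannot be told apart from a gain of other cells.

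The naive-marker-low cells fell into several clusters. A proliferating-like cluster with Mki67, Top2a and Birc5, genes of dividing cells, held 18.2% of anti-CD137 cells on day 11 (17.2 to 19.3) and 16.8% on day 18 (15.9 to 17.7), against 0.178% and 0.354% of control cells. An exhausted-like cluster led by Ccl4, Ccl3, Tnfrsf9, Nr4a2, Pdcd1 and Havcr2 held 3.57% (3.08 to 4.11) and 21.1% (20.1 to 22.1), against 0.0178% and 0.558%. This share depended on the clustering: in other clusterings and with stricter cells, clusters with Ccl5 among their leading genes also took the name, and exhausted-like cells held 6.10% to 51.6% on day 11 and 59.2% to 70.3% on day 18, against at most 0.392% and 4.15% of control cells. A cluster led by Ccl5, S100a6, Gzmk and Gzmb, with markers of effector and of exhausted cells and therefore left unnamed, held 45.8% and 47.3%, against 0.357% and 3.48%. Interferon-responding-like cells with low naive markers held 1.73% and 3.79%, against 0.963% and 2.38%. Memory-like cells, led by Gzmm, Klrk1, Xcl1, Ly6c2 and Cxcr3, made up 9.13% (8.39 to 9.91) of control cells on day 11 and 14.1% (13.2 to 15.1) on day 18, and 15.8% (14.9 to 16.9) and 7.77% (7.15 to 8.43) under anti-CD137. Only 39 cells in all libraries were B cells-like. Over the 3 day pairs the share of naive-marker-high cells differed by −50.4 points on average and was lower in 3 of 3 pairs, with an exact two-sided sign-flip permutation p of 0.25, the smallest that 3 pairs can give. The difference for naive-marker-low cells was 49.99 points (exact permutation p = 0.5) with −0.0164 points on day 1, and for memory-like cells 0.461 points (exact permutation p = 0.75), with a sign that depended on the clustering (−3.56 to 2.99).

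**Figure D1:**
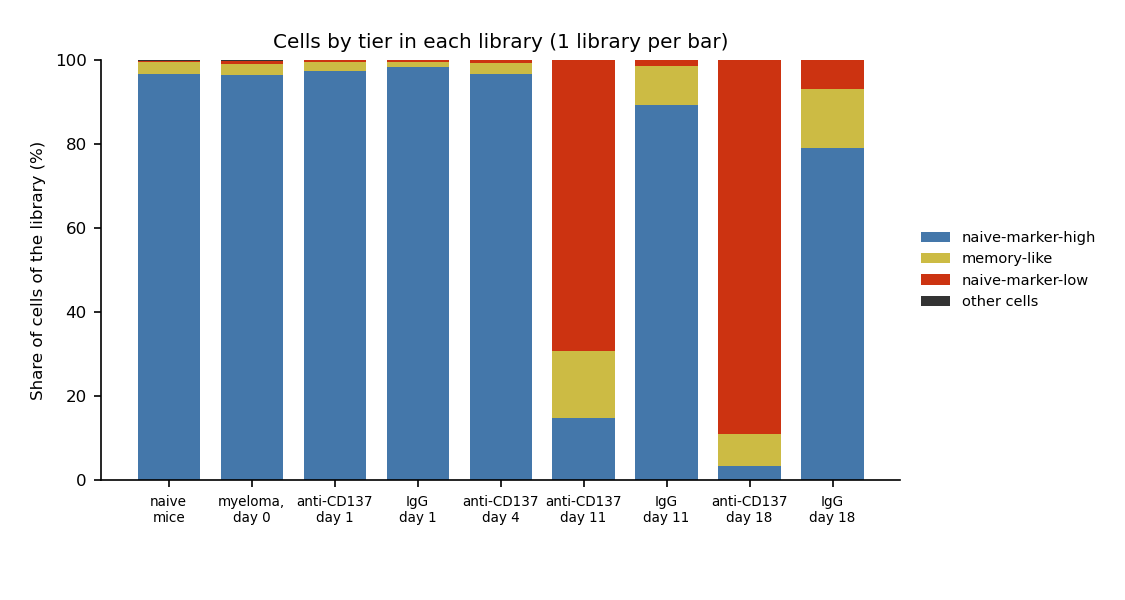
Share of cells (%) in each tier, with 1 bar per library and colours for the tiers. Naive-marker-high cells fill 79.1% or more of every bar except the anti-CD137 libraries of days 11 and 18, where they fill 14.8% and 3.25%.

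Anti-CD137 was first compared with control IgG averaged over days 1, 11 and 18 in all CD8 T-like cells, to ask which genes responded to the agonist whatever the day. Genes of killing and of T cell inhibition were higher and genes of naive T cells were lower on average, with effects near 0 on day 1 and large on days 11 and 18. The make-up by tier differed between the arms on days 11 and 18 and enters these differences. Gzmb, a cytotoxic granule protease, differed by 2.88 ± 1.06 (log2, SE, 3 pairs), with log2 ratios of −0.21, 4.87 and 3.96 on the 3 days. Pdcd1, the inhibitory receptor PD-1, differed by 2.41 ± 0.81 (0.02, 3.69 and 3.52). Ccr7, which guides naive T cells to lymph nodes, differed by −1.93 ± 0.71 (0.03, −2.33 and −3.48). With limma, 0 of 8535 genes passed the threshold, the smallest adjusted p was 0.263, and 1427 genes had an unadjusted p under 0.05.

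As groups, 11 of the 17 programme lists passed the camera test at its preset correlation, and 0 passed with an estimated correlation, where the smallest adjusted p was 0.604, or with fry, where it was 0.267. All 16 measured cytotoxic effector genes were higher on average, with a median log2 difference of 1.74 (adjusted p = 0.000298, adjusted p = 0.604 with an estimated correlation). Gzmk differed by 3.00, Ccl5 by 2.72 and Ccl3 by 2.71. All 17 genes of inhibitory receptors and exhaustion were higher, with a median of 1.39 (adjusted p = 2.43e-05, adjusted p = 0.604 with an estimated correlation), among them Lag3 at 2.30 and Tox, a transcription factor of exhausted T cells, at 1.72. Of 14 terminal effector genes 11 were higher (median 1.03, adjusted p = 0.0387, adjusted p = 0.607 with an estimated correlation), led by the calcium-binding S100a4 at 3.25. Of 16 naive and stem-like memory genes 15 were lower (median −1.23, adjusted p = 1.17e-07, adjusted p = 0.604 with an estimated correlation), including Dapl1 at −1.97 and Il7r, the receptor for the survival cytokine IL-7, at −1.90.

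Cell cycle, interferon and metabolic genes were higher as well. Of 23 cell cycle genes 22 were higher (median 1.10, adjusted p = 2.43e-05, adjusted p = 0.604 with an estimated correlation), with Pclaf at 1.99 and Stmn1 at 1.96. All 19 genes of the interferon gamma response and antigen presentation were higher (median 0.76, adjusted p = 7.06e-06, adjusted p = 0.604 with an estimated correlation), with Tap1, a peptide transporter, at 0.92. Of 22 type I interferon genes 20 were higher (median 0.42, adjusted p = 0.000415, adjusted p = 0.604 with an estimated correlation). Glycolysis (13 of 14 genes, median 0.38, adjusted p = 0.00410) and oxidative phosphorylation (all 19 genes, median 0.44, adjusted p = 0.00165) were higher, each with adjusted p = 0.604 with an estimated correlation. All 20 cytosolic ribosomal protein genes were lower (median −0.46, adjusted p = 1.36e-07, adjusted p = 0.604 with an estimated correlation). Of 11 T cell receptor immediate early genes 10 were lower (median −0.47, adjusted p = 8.71e-06, adjusted p = 0.604 with an estimated correlation), and 4 of them passed when adjusted over the list alone. Fos, a transcription factor switched on within minutes of stimulation, was lower on each day (−1.65, −1.37 and −2.89). In the lists of T cell programmes named so far, no other member passed in that way or over all genes.

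The other programme lists did not pass. The median was 0.24 for NF-kB and TNF receptor signalling targets (adjusted p = 0.130), 0.41 for TNF receptor superfamily costimulation (0.115), −0.13 for interleukin 2 and STAT5 targets (0.0835), 0.90 for tissue residency and chemokine receptors (0.506) and 0.14 for heat shock and dissociation stress (0.495). For NK-type receptors on T cells the median was 0.27 while the test pointed down (0.926). Tnfrsf9, which encodes CD137 itself, differed by 1.93 ± 0.64 (0.14, 2.38 and 3.27), and the T cell genes Cd3e by 0.43 and Cd8a by 0.25. Among lists of other cell types, erythroid genes were lower (5 of 6, median −0.27, adjusted p = 0.0402, adjusted p = 0.339 with an estimated correlation). Genes of plasma cells and myeloma cells (median 1.43, adjusted p = 0.0659, with 3 higher when adjusted over the list alone), B cells (−0.79, 0.209, with 1 higher and 2 lower over the list alone) and monocytes and macrophages (0.98, 0.209) did not pass. Too few genes were measured to test the lists of neutrophils, NK cells, CD4 T cells, gamma-delta T cells, dendritic cells and stem and progenitor cells. Day 1 decided the count of genes: without that pair 3782 genes passed (2662 higher and 1120 lower), and the 1 library per arm and day means that the test reads the spread of the effect between days. With no block for day, 0 genes passed in limma and 368 had an unadjusted p under 0.05.

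The same test in non-naive CD8 T-like cells asked which genes differed once naive-marker-high cells were set aside. These cells were mostly memory-like under control IgG (512 of 597 on day 11 and 758 of 1122 on day 18) and mostly naive-marker-low under anti-CD137 (3572 of 4389 and 6057 of 6586), so the make-up by tier enters the differences, and within tiers that by cluster. Genes of dividing cells, PD-1 and the ectonucleotidase Entpd1 were higher with anti-CD137, while Il7r, naive genes and type I interferon genes were lower. Entpd1, which encodes CD39, differed by 1.38 ± 0.19 (log2, SE, 3 pairs; 1.09, 1.84 and 1.21 on the 3 days), and Pdcd1 by 1.78 ± 0.39. Slfn5, an interferon-induced gene, differed by −1.86 ± 0.30 (−0.98, −2.05 and −2.54). Levels within tiers were chosen after seeing the data. Within memory-like cells Pdcd1 stood at 30.8 CPM against 6.15 on day 11 and 45.1 against 6.45 on day 18, and Il7r at 162 against 342 and 200.4 against 372, but Entpd1 was near equal or lower (7.38 against 7.17, 9.01 against 11.9), and Isg15 was not lower throughout (89.2 against 92.2, 148 against 112). Within naive-marker-low cells Isg15 stood at 175 against 1839 and 251 against 665, and Entpd1 at 68.7 against 18.8 and 107 against 95.002, where 89 of 3572 and 258 of 6057 anti-CD137 cells were interferon-responding-like, against 54 of 85 and 128 of 364 control cells. With limma, 0 of 8733 genes passed, the smallest adjusted p was 0.250, and 1279 genes had an unadjusted p under 0.05; the adjusted p of these 3 genes was 0.250 to 0.257.

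At the preset correlation 12 of 17 programme lists passed, and 0 with an estimated correlation (smallest adjusted p 0.537) or with fry (0.267). Cell cycle genes led (23 of 24 higher, median 1.03, adjusted p = 4.26e-12, adjusted p = 0.537 with an estimated correlation; 15 higher when adjusted over the list alone), with Pclaf at 1.64 and Birc5 at 1.56. Naive and stem-like memory genes were lower (15 of 16, median −1.04, adjusted p = 2.51e-07, adjusted p = 0.537 with an estimated correlation; 8 lower over the list alone), with Il7r at −2.06 and Satb1 at −1.92. Type I interferon genes were lower here (18 of 22, median −0.39, adjusted p = 9.22e-05, adjusted p = 0.537 with an estimated correlation; 9 lower over the list alone), with Ifit3 at −1.08, Oasl2 at −1.07 and Rsad2 at −1.04. The smaller part of interferon-responding-like cells among non-naive cells with anti-CD137 (89 of 4389 on day 11 and 258 of 6586 on day 18, against 54 of 597 and 128 of 1122) enters this difference. The interferon gamma list had a median of 0.12 and did not pass (0.0504). Genes of inhibitory receptors and exhaustion were higher (15 of 17, median 0.66, adjusted p = 5.16e-05, adjusted p = 0.550 with an estimated correlation; 3 over the list alone), and so were cytotoxic genes (12 of 16, median 0.63, adjusted p = 0.0351, adjusted p = 0.550 with an estimated correlation). Immediate early genes were lower (10 of 12, median −0.68, adjusted p = 0.000278, adjusted p = 0.537 with an estimated correlation; 6 lower and 1 higher over the list alone), with Fos at −1.70.

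Metabolic lists moved with them: oxidative phosphorylation (18 of 19 higher, median 0.30, adjusted p = 0.000149, adjusted p = 0.550 with an estimated correlation) and glycolysis (11 of 14 higher, median 0.20, adjusted p = 0.00761, adjusted p = 0.537 with an estimated correlation). Ribosomal protein genes (20 of 20, median −0.37, adjusted p = 0.00102, adjusted p = 0.612 with an estimated correlation), interleukin 2 and STAT5 targets (9 of 12, median −0.48, adjusted p = 0.0162, adjusted p = 0.550 with an estimated correlation) and NK-type receptors (11 of 12, median −0.49, adjusted p = 0.0162, adjusted p = 0.612 with an estimated correlation) were lower. NF-kB and TNF receptor signalling targets were higher (11 of 17, median 0.21, adjusted p = 0.0403, adjusted p = 0.537 with an estimated correlation). The lists of terminal effector differentiation (median −0.02, mean 0.29, adjusted p = 0.658; 4 higher and 3 lower over the list alone), TNF receptor superfamily costimulation (0.14, 0.234), tissue residency (−0.13, 0.658) and heat shock (0.06, 0.485) did not pass. Plasma cell and myeloma cell genes were higher (3 of 3, median 0.63, adjusted p = 0.00312, adjusted p = 0.434 with an estimated correlation). Monocyte (0.86, 0.0632), erythroid (−1.80, 0.0632), gamma-delta T cell (−0.85, 0.0664), dendritic cell (−0.46, 0.255) and B cell genes (−0.77, 0.312) did not pass at the preset correlation, nor did NK cell genes (0.516), whose median was −0.08 while the test pointed up. With fry, plasma cell (adjusted p = 0.0408) and monocyte genes (0.0408) passed upward and dendritic cell genes (0.00407) downward. These lists include leading genes of T cell clusters here. Slamf7 of the plasma cell list led the memory-like cluster, and Ccr2 of the monocyte list the unnamed naive-marker-low cluster. Ccr9 and Bst2 of the dendritic cell list led naive-marker-high clusters. A list that passed therefore does not show transcripts of another cell type. The control library of day 1 held 87 non-naive cells, and when 87 cells were drawn from each library 45 genes passed (24 higher and 21 lower). Leaving out 1 day gave 3014 genes without day 1, 22 without day 11 and 55 without day 18, and with no block for day 0 genes passed in limma, with 552 at an unadjusted p under 0.05.

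The late effect of anti-CD137 (days 11 and 18) was tested against its early effect (day 1) in all CD8 T-like cells, to ask which responses needed time. The effect was larger late for exhaustion, cytotoxic and cell cycle genes and more negative late for naive genes. With anti-CD137, naive-marker-low cells were 29 of 5201 CD8 T-like cells on day 1. They were 3572 of 5153 on day 11 and 6057 of 6807 on day 18. The make-up by tier therefore enters these effects, which do not show changes per cell. The errors given rest on the disagreement between days 11 and 18, moderated over genes. They hold no spread of the single day 1 pair or between mice. Pdcd1 (chromosome 1, 94038305 to 94052553) rose by 3.58 ± 0.14 more late than early (log2, SE, 6 libraries; adjusted p = 0.00297), and Lag3, another inhibitory receptor (chromosome 6, 124904361 to 124911705), by 3.52 ± 0.14 (0.00297). Gzmb (chromosome 14, 56258838 to 56262260) rose by 4.62 ± 0.37 more late (0.00473) and S100a4 by 4.67 ± 0.47 (0.00844). The test called 1010 of 8535 genes, 768 with a more positive and 242 with a more negative late effect, and 2614 had an unadjusted p under 0.05. The other 8 genes among the 10 smallest p values were Casp1 (2.80), a protease of inflammasomes, Serpina3g (3.66), the cell cycle gene Ube2c (2.78), Plek (2.65), Chst2 (2.73), Ptms (2.74), Osbpl3 (2.77) and the transcription factor Irf8 (2.42), each with an adjusted p of 0.00297. Serpina3g has close paralogs that share reads with it.

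Of 17 programme lists 10 passed at the preset correlation, and 0 with an estimated correlation (smallest adjusted p 0.540) or with fry (0.117). Of 17 exhaustion genes 15 rose late (17 when adjusted over the list alone; median 2.10, adjusted p = 6.50e-12, adjusted p = 0.540 with an estimated correlation), including Tox (2.77) and Bhlhe40 (2.73). Of 23 cell cycle genes 18 rose (21 over the list alone; median 1.75, adjusted p = 1.52e-10, adjusted p = 0.540 with an estimated correlation), including Pclaf (2.98), Ccnb2 (2.81) and Birc5 (2.80). Of 16 naive genes 8 fell (14 over the list alone; median −1.86, adjusted p = 1.14e-09, adjusted p = 0.540 with an estimated correlation), led by Ccr7 (−2.94), Dapl1 (−2.86), Satb1 (−2.68) and Lef1 (−2.51). Of 16 cytotoxic genes 11 rose (13 over the list alone; median 2.66, adjusted p = 1.83e-07, adjusted p = 0.540 with an estimated correlation), including the chemokines Ccl4 (4.42) and Ccl3 (4.12), paralogs of each other, and Gzmk (4.37). Of 14 terminal effector genes 8 rose (11 up and 2 down over the list alone; median 1.64, adjusted p = 0.000995, adjusted p = 0.695 with an estimated correlation), including Klrg1 (3.28), a receptor of short-lived effector cells.

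Among interferon gamma genes 8 of 19 rose (14 over the list alone; median 0.82, adjusted p = 1.42e-06, adjusted p = 0.540 with an estimated correlation), with Tap1 at 1.43, Psmb9 at 1.25 and Irf1 at 1.20. Among type I interferon genes 4 of 22 rose (9 up and 1 down over the list alone; median 0.51, adjusted p = 0.00945, adjusted p = 0.540 with an estimated correlation), with Zbp1 at 1.27. Glycolysis (2 of 14 rose, 3 over the list alone; median 0.41, adjusted p = 0.0222, adjusted p = 0.707 with an estimated correlation; Gapdh 1.39) and oxidative phosphorylation (2 of 19 rose, 2 over the list alone; median 0.43, adjusted p = 0.0400, adjusted p = 0.540 with an estimated correlation; Ndufb8 0.98) passed too. Ribosomal protein genes were lower as a list (20 of 20, median −0.67, adjusted p = 7.20e-07, adjusted p = 0.540 with an estimated correlation), with 0 called singly in limma. Lists that did not pass held single calls. Ccr2 (3.22), a receptor for inflammatory chemokines, rose and Ccr9 (−2.70), a gut-homing receptor, fell in the tissue residency list (5 up and 4 down, 8 and 4 over the list alone; median 1.10, adjusted p = 0.263). Tnfrsf9 rose by 2.69 ± 0.36 (0.0149) and Tnfsf8 fell by 1.94 in the TNF receptor superfamily list (2 up and 1 down, 5 and 1 over the list alone; median 0.62, 0.113). Bcl2a1b (2.24), a survival gene with close paralogs, rose among NF-kB targets (2 up, 4 over the list alone; median 0.31, 0.0694), Il2rb (1.70) rose and Socs3 (−1.02) fell among interleukin 2 targets (2 up and 1 down, 3 and 3 over the list alone; median −0.29, 0.0893), and Nr4a2 (2.10) rose among immediate early genes (1 up, 1 and 2 over the list alone; median −0.19, 0.203).

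Heat shock genes had a median of 0.11 and a mean of −0.06 (adjusted p = 0.285), and NK-type receptors a median of 0.36 while the test pointed down (0.917). All 3 measured plasma cell and myeloma cell genes rose (median 2.07, adjusted p = 0.0165, adjusted p = 0.686 with an estimated correlation). That list includes Slamf7, a leading gene of the memory-like cluster. B cell genes (median −1.12, 0.0730, 2 fell), monocyte genes (1.41, 0.206, 2 rose) and erythroid genes (median 0.13 while the test pointed down, 0.656) did not pass. Cd3e (0.64, adjusted p = 0.159) and Cd8a (0.39, 0.481) were not called. The calls rest on 1 early pair and 1 residual degree of freedom, so the test could not be repeated without single days. Without the filter on low values 0 of 13861 genes passed in limma (2992 at an unadjusted p under 0.05), and Pdcd1 then had an adjusted p of 0.112.

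On day 1, anti-CD137 was compared with control IgG to find the earliest response, 1 library against 1 without a test. Immediate early genes were lower and heat shock genes slightly higher, and T cell effector genes were close to equal. Fos (chromosome 12, 85473890 to 85477273) stood at 12.5 CPM with anti-CD137 and 60.4 with control IgG (log2 ratio −1.65), its partner Jun at 48.5 and 99.5 (−0.91), Junb at 158 and 248 (−0.62) and Cd69, a surface marker of recent stimulation, at 66.1 and 93.4 (−0.44). Tnfrsf9 stood at 6.22 and 4.75 (0.14), Cd8a at 595 and 600.1, and Cd3e at 729 and 724.

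Of 16 measured programme lists, 9 lay outside the range of random lists, 7 above and 2 below. Immediate early genes had a median of −0.44 (9 of 10 lower; random lists −0.05 to 0.07) and naive genes −0.07 (13 of 16 lower; Il7r −0.27). Above the range lay heat shock (median 0.23, 8 of 9 higher; the chaperones Dnaja1 at 361 and 269, Dnajb1 0.37, Hspa8 0.28), type I interferon (0.14, 14 of 17; Isg15 at 54.1 and 40.6), cytotoxic effector genes (0.13, 5 of 6; Ccl5 at 173 and 140), oxidative phosphorylation (0.11, 15 of 19; Atp5k 0.31), interferon gamma (0.08, 14 of 18), cell cycle (0.08, 9 of 12) and TNF receptor superfamily genes (0.07, 6 of 8; Tnfsf8 0.31). In non-naive cells only, medians turned negative for cytotoxic (−0.31), type I interferon (−0.19), interferon gamma (−0.17), TNF receptor superfamily (−0.025) and oxidative phosphorylation genes (−0.0023). Inside it lay terminal effector (0.01), exhaustion (0.03), NF-kB (0.04), interleukin 2 (0.03), glycolysis (0.05), ribosomal protein (−0.04) and tissue residency genes (0.01). Erythroid genes were lower (median −0.42, 5 of 6; haemoglobin Hbb-bs at 54.7 and 106), but in naive-marker-high cells only, a run chosen after seeing the data, the median was 0.071 and Hbb-bs stood at 56.1 and 56.5, while it stood at 4.78 and 4526 in memory-like cells, of which the control library held 56. Other genes at the extremes were the cold-induced Cirbp (−0.67), the splicing factor Srsf5 (−0.56) and the stress gene Ppp1r15a (−0.54) among the lower, and the dynein light chain Dynll1 (0.40) and the memory marker Ly6c2 (0.38) among the higher.

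On day 11, the comparison asked how the arms differed after repeated doses. In all CD8 T-like cells, cytotoxic and inhibitory genes were many times higher with anti-CD137. Gzmb stood at 624 CPM against 11.6 with control IgG (log2 ratio 4.87), Gzmk, another granzyme, at 657 against 9.31 (5.11), Ccl5 at 26891.5 against 1271 (4.39), Pdcd1 at 145 against 2.02 (3.69) and Klrg1 at 120.2 against 1.08 (3.55). The naive genes Ccr7 (57.8 against 332), Satb1 (52.0 against 292), Dapl1 (122 against 613) and Lef1 (109 against 473) were lower, with log2 ratios of −2.33 to −2.02. Cd8a was near equal (599 and 588), Cd3e stood at 913 and 650.3, and Tnfrsf9 at 84.8 against 8.27 (2.38). Naive-marker-low cells were 3572 of 5153 CD8 T-like cells with anti-CD137 and 85 of 5608 with control IgG. The make-up by tier therefore enters these ratios. Within naive-marker-low cells, chosen after seeing the data, Gzmb stood at 881 CPM against 464 and Pdcd1 at 201 against 72.0. Of the cytotoxic list, Gzmm (14.4 against 62.6), Xcl1 (23.4 against 125), Tnf (3.87 against 25.1) and Ctsw (417 against 482) were lower there. The other cytotoxic genes were higher. Interferon-responding-like cells were 54 of these 85 control cells and 89 of the 3572 anti-CD137 cells. The make-up by cluster therefore enters these values too.

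Of 17 programme lists 4 lay above the random range and 6 below in non-naive cells only. In naive-marker-low cells only, chosen after seeing the data, 5 lay above and 9 below. In all CD8 T-like cells 15 lay outside, 11 above and 4 below. The highest were cytotoxic (median 2.74, 16 of 16 higher), exhaustion (2.07, 15 of 15; Lag3 at 125 against 2.91, Tox at 224 against 28.6), terminal effector (1.54, 12 of 14; S100a4 at 889 against 11.3, S100a6 at 2069 against 61.6), cell cycle (1.44, 21 of 23; Ccnb2 3.12, Birc5 3.02) and tissue residency (1.21, 10 of 14; Ccr2 3.52, Ccr9 −2.15). Interferon gamma (0.91, 19 of 19; Tap1 at 257 against 98.7), oxidative phosphorylation (0.65, 19 of 19), NK-type receptor (0.61, 5 of 7), type I interferon (0.59, 18 of 20), glycolysis (0.49, 13 of 14; Gapdh at 1598 against 640) and TNF receptor superfamily genes (0.49, 7 of 8) were higher too. In non-naive cells only, the direction turned for NK-type receptor (−0.89), type I interferon (−0.55), terminal effector (−0.13) and tissue residency genes (−0.045), and for the list of NK cells (−0.87). Naive (−1.36, 15 of 16), ribosomal protein (−0.72, 20 of 20; Rps24 at 8668 against 17056), immediate early (−0.37, 8 of 10; Jun at 41.7 against 167) and interleukin 2 genes (−0.14, 8 of 12; Ltb −0.93, though Il2rb 1.82) were lower. In naive-marker-high cells only, chosen after seeing the data, the interleukin 2 median (0.29) turned positive, and the glycolysis (−0.099) and TNF receptor superfamily medians (−0.0034) and Igkc (−0.36) turned negative. NF-kB (0.26) and heat shock genes (median 0.01, mean −0.011) lay inside. Lists of other cell types included plasma cells and myeloma cells (2.49, 3 of 3; Igkc, the constant part of the immunoglobulin kappa light chain, at 308 against 16.8), neutrophils (1.57, 4 of 4; S100a9 at 70.1 against 10.0), monocytes (1.60), NK cells (1.56; Eomes, which CD8 T cells also express, at 180.2 against 27.6), erythroid (−0.60) and dendritic cells (median 0.59, mean −0.24, inside). Ighm, the IgM heavy chain, was lower (123 against 326). The plasma cell list includes Slamf7 and the monocyte list Ccr2, both leading genes of T cell clusters here. The median of all genes was 0.12 here and 0.03 with TMM scaling, so ratios near 0.12 do not stand out.

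On day 18, the same comparison followed the response after a longer treatment. In all CD8 T-like cells, exhaustion genes were the highest group and naive genes lay further down than on day 11. Pdcd1 stood at 303 CPM against 17.4 (log2 ratio 3.52), Lag3 at 279.5 against 14.7 (3.55), Havcr2, the inhibitory receptor TIM-3, at 136 against 9.12 (2.93) and Tox at 423 against 57.6 (2.68). Il7r stood at 48.1 against 625 (−3.45), Dapl1 at 32.2 against 503 (−3.60) and Ccr7 at 14.6 against 265 (−3.48). Tnfrsf9 stood at 201 against 11.9 (3.27), Cd8a at 909 against 542 (0.74) and Cd3e at 937 against 529 (0.81). Naive-marker-low cells were 6057 of 6807 CD8 T-like cells with anti-CD137 and 364 of 5371 with control IgG. The make-up by tier therefore enters these ratios. Within naive-marker-low cells, chosen after seeing the data, Pdcd1 stood at 336 CPM against 239 and Lag3 at 311 against 195. Havcr2 stood at 152 against 134 there, and Tox at 462 against 327. Cd200r1 (34.2 against 78.8), Cd101 (26.9 against 30.9) and Tox2 (28.4 against 30.1) were lower. Interferon-responding-like cells were 128 of these 364 control cells and 258 of the 6057 anti-CD137 cells. The make-up by cluster therefore enters these values too.

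Of 17 lists 6 lay above the random range and 7 below in non-naive cells only. In naive-marker-low cells only, chosen after seeing the data, 4 lay above and 7 below. In all CD8 T-like cells 14 lay outside, 10 above and 4 below. Above lay exhaustion (median 2.46, 17 of 17), cytotoxic (2.35, 14 of 16; Gzmb at 784 against 41.0, Ccl4 at 1470.5 against 103), cell cycle (1.79, 23 of 24; Pclaf 3.33, Mki67 at 121 against 5.69, Top2a 2.84), terminal effector (1.32, 11 of 14; S100a4 at 495 against 17.2), interferon gamma (1.14, 19 of 19; Tap1 at 369 against 124, Irf1 1.49), tissue residency (0.70, 10 of 14; Cxcr6, which keeps T cells in tissue, at 469 against 115), type I interferon (0.68, 19 of 22), TNF receptor superfamily (0.67, 8 of 9), glycolysis (0.59, 13 of 14; Gapdh at 1902 against 617) and NF-kB genes (0.41, 12 of 17). In non-naive cells only, the type I interferon (−0.20) and tissue residency medians (−0.46) turned negative. Below lay naive (−2.41, 15 of 16), immediate early (−0.75, 10 of 12; Fos at 3.44 against 89.4, though Nr4a2 at 95.1 against 9.12), ribosomal protein (−0.68, 20 of 20; Rps24 −1.23) and interleukin 2 genes (−0.60, 7 of 11). In naive-marker-high cells only, chosen after seeing the data, ribosomal protein (0.12) and interleukin 2 medians (0.52) turned positive, and the plasma cell median (−0.48), Igkc (−0.77) and Havcr2 (−0.028) turned negative. Oxidative phosphorylation (0.35), NK-type receptor (−0.10) and heat shock genes (0.32) lay inside. Plasma cell (1.23, 3 of 4 higher; Igkc at 305 against 35.4, but the heavy chain Ighg2b at 0 against 20.5), monocyte (1.31) and B cell lists (−1.24; Ighm at 72.5 against 301) lay outside, and dendritic cell genes inside (median 0.63, mean −0.54).

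**Figure D2:**
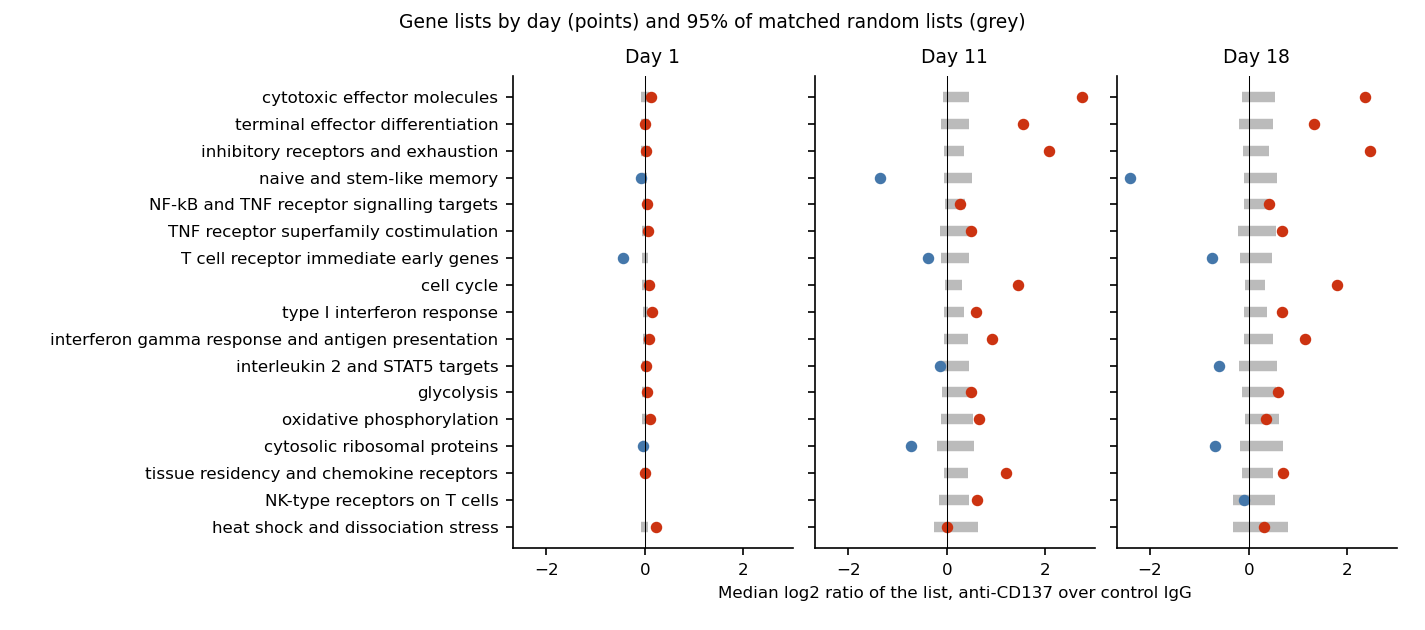
Median log2 ratio of anti-CD137 over control IgG for each gene list (points) on days 1, 11 and 18, with the central 95% of matched random lists in grey. The cytotoxic list lies at 0.13, 2.74 and 2.35 on the 3 days and the naive list at −0.07, −1.36 and −2.41.

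**Figure D3:**
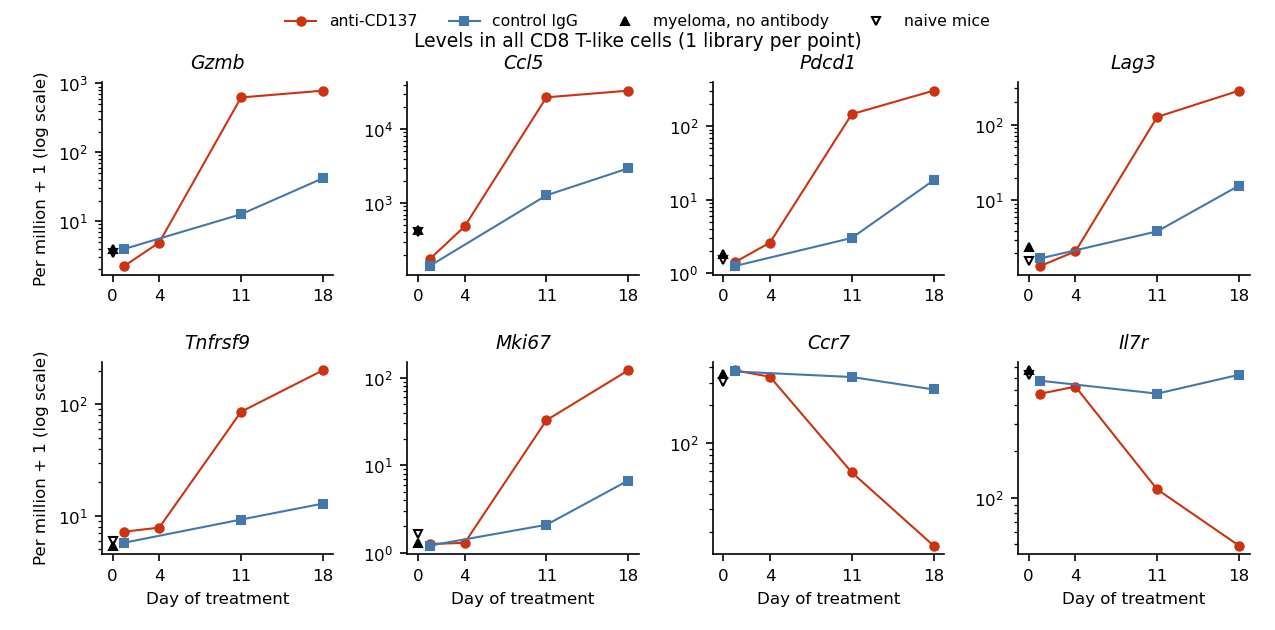
Level in CPM plus 1 (log scale) of 8 genes against day of treatment, with 1 library per point, red for anti-CD137, blue for control IgG and black marks for untreated mice. Gzmb stands at 624 and 784 CPM on days 11 and 18 with anti-CD137 and at 11.6 and 41.0 with control IgG.

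Myeloma-bearing mice 10 days after transfer were compared with naive mice to ask what the tumour alone did before treatment, 1 library against 1. T cell programmes were close to equal, while haemoglobin transcripts were higher and immediate early transcripts lower with myeloma. Hbb-bs stood at 372 CPM against 11.9 (log2 ratio 4.13) and Hba-a1 at 104 against 3.60 (3.06); the haemoglobin genes are paralogs that share reads. Junb stood at 379 against 573 (−0.58), Ier2 differed by −0.41 and Fos by −0.34. In naive-marker-high cells Hbb-bs stood at 351 CPM in this myeloma library. It stood at 56.5, 35.1 and 0.393 in the control IgG libraries of days 1, 11 and 18, also of myeloma-bearing mice. The immediate early median differed by −0.55 between the control IgG library of day 1 and this library, neither given the agonist. Both differences are thus mixed with differences between libraries. Cd28, a costimulatory receptor, was slightly higher (0.26), Tnfrsf9 stood at 4.41 against 4.89, and Cd8a (−0.03) and Cd3e (0.15) were near equal.

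Of 16 programme lists 5 lay outside the random range, 1 above and 4 below: TNF receptor superfamily (median 0.18, 6 of 7 higher), immediate early (−0.30, 8 of 11 lower), oxidative phosphorylation (−0.07, 12 of 19 lower; Atp5k at 94.8 against 161), exhaustion (−0.05, 4 of 5 lower) and NF-kB genes (0.03, below random lists at 0.04 to 0.14). Erythroid genes were higher (2.80, 6 of 6). Inside lay cytotoxic (0.11), terminal effector (0.15), naive (0.08), cell cycle (0.13), type I interferon (0.05), interferon gamma (0.07), interleukin 2 (0.02), glycolysis (0.07), ribosomal protein (0.07), tissue residency (0.08) and heat shock genes (0.04). The glucocorticoid-induced Tsc22d3 was higher (531 against 389) and the ribosomal pseudogene Gm10076 lower (407 against 979.9). In non-naive cells only, the exhaustion median was 0.11.

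Control IgG on day 18 was compared with untreated myeloma on day 0 to follow the disease without the agonist. In all CD8 T-like cells, cytotoxic, interferon and inhibitory genes were higher on day 18. Memory-like cells were 149 of 5699 CD8 T-like cells on day 0 and 758 of 5371 on day 18. Naive-marker-low cells were 35 and 364 of them. The make-up by tier therefore enters the ratios below. The day 18 libraries of both antibodies also stood apart from all other libraries in genes such as Gm42418 (896 and 674 CPM with control IgG and anti-CD137, against 195 to 292), Dhx9 (136 and 129, against 49.2 to 71.0) and Erbin (86.3 and 111, against 27.6 to 38.8), so a library difference of that day is mixed with time. Ccl5 stood at 2945 CPM against 436 (log2 ratio 2.73), Ccl4 at 103 against 4.26 (2.98), Ly6c2 at 429 against 151 (1.45) and Xcl1, a chemokine for dendritic cells, at 62.7 against 11.9 (1.73). Isg15 stood at 89.3 against 36.9 (1.08), Ifit3 at 60.7 against 23.6 (1.08), Tox at 57.6 against 32.5 (0.67) and Tnfrsf9 at 11.9 against 4.41 (0.60). Hbb-bs stood at 0.410 against 372 (−5.20), Cd3e differed by −0.41 and Cd8a by 0.08. In naive-marker-high cells the day 0 library held the most Hbb-bs of all libraries (351 CPM, against 0.393 to 56.5). A library difference of day 0 is thus mixed with the change in Hbb-bs.

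Of 17 lists 11 lay outside, 10 above and 1 below. Above lay cytotoxic (median 1.44, 15 of 15 higher), terminal effector (0.89, 8 of 10), exhaustion (0.67, 11 of 11), type I interferon (0.65, 21 of 21), tissue residency (0.56, 8 of 13), NK-type receptor (0.37, 2 of 3), interferon gamma (0.35, 17 of 19), NF-kB (0.26, 14 of 16), heat shock (0.24, 7 of 9) and glycolysis genes (0.20, 12 of 14), and below lay naive genes (−0.16, 15 of 16). Inside lay TNF receptor superfamily (0.09), immediate early (0.15), cell cycle (0.16), interleukin 2 (0.16), oxidative phosphorylation (0.04) and ribosomal protein genes (−0.05). Plasma cell genes were higher (1.55, 4 of 4) and erythroid genes lower (−3.20, 6 of 6). Values between came from the control libraries of days 1 and 11 against the same day 0 library: the cytotoxic median was 0.02 (mean −0.30) and 0.59, and the erythroid median −1.61 and −2.52. In non-naive cells only, 4 lists lay outside, and the terminal effector (−0.17) and interferon gamma medians (−0.093) turned negative, as did Isg15 (−0.30), Ifit3 (−0.077), Ly6c2 (−0.070), Cxcr3 (−0.030) and Ly6a (−0.00058). In naive-marker-high cells only, chosen after seeing the data, the terminal effector (−0.39) and tissue residency medians (−0.074) did.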

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

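The test of late against early effects was planned before the data were examined, with days 1 and 4 as early days, and was run with day 1 alone. It was singled out because the effect of anti-CD137 differed between days: 1010 genes had another effect on days 11 and 18 than on day 1 in limma, 768 more positive and 242 more negative. Over the other settings the count ran from 0 without a filter on low values to 1171 with median-of-ratios scaling. In the same libraries naive-marker-low cells made up 0.558% of anti-CD137 cells on day 1, 69.3% on day 11 and 89.0% on day 18, so a changed make-up of the cells and changes within cells add up in this count. No technical explanation was weighed for it.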

How the results depend on the processing

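The runs on naive-marker-high cells and on naive-marker-low cells only, those with pseudocounts of 1 and 50 CPM in the averaged and late-against-early tests, TMM scaling of non-naive cells and of the late-against-early test, and the clustering without the listed genes were chosen after seeing the data. Of 38 repeats of the counts of called genes, 30 stayed within 1.5-fold of the first count, 5 lay above that and 3 below. In the averaged tests the first count was 0, so staying meant 0 again, which says little of robustness. In the late-against-early test, counts of 734 to 1171 fell within 1.5-fold of 1010. Of 35 repeats of the counts of lists outside their range, 30 stayed within 1.5-fold. By the labels used, 503 of 853 list medians and 4141 of 5282 gene values stayed the same. For values from tests this meant the same side of the threshold, with the sign compared only where a call was made and the size not compared. For single libraries it meant a shift smaller than the spread of random lists or, for genes, of the libraries up to day 4. The share differences of naive-marker-high (−46.0 to −53.0 points over the clusterings) and naive-marker-low cells kept their sign in every repeat. Those of memory-like cells (0.461 points) did not, with −3.56 to 2.99 over the clusterings and −2.67 to 3.86 on leaving out a day, nor did those of other cells (−0.0054, to 0.0133 at resolution 0.6). Not run were the DESeq2 Wald test and thinning, which need raw counts, a run without the few cells marked as doublets, and leave-one-out for the late-against-early test, which would have no residual degrees of freedom. Depth limits are unknown because the values were equalised. Except where fewer or other cells are part of the setting, the cause was not tested.

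In the averaged test of all CD8 T-like cells, leaving out a day gave 0 to 3782 genes (3782 without day 1). In non-naive cells it gave 22 to 3014 genes (3014 without day 1, 22 without day 11 and 55 without day 18, against 0 with all), and equal numbers of cells gave 45. For the late-against-early test, no low-value filter gave 0 genes in limma (2992 at an unadjusted p under 0.05, against 2614 with the filter, and more genes tested), stricter cells 545 and a pseudocount of 50 CPM 648, of which 539 and 647 were the same genes as the 1010. Of 11 lists past the threshold, 0 remained with an estimated correlation and 0 with fry. Leaving out a day gave −37.7 to −75.2 points for the share of naive-marker-high cells and 33.9 to 74.99 for naive-marker-low cells. The 6 libraries can be split into 10 groupings of 3 and 3, too few for a share under 0.05. Of these, 10 gave at least the real 0 genes in all CD8 T-like cells (highest other 0) and 10 in non-naive cells, where the highest other gave 4 (limma; real 1427 and 1279 genes at an unadjusted p under 0.05, highest other 835 and 1290).

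With stricter cells, 5 lists stood out on day 1 in place of 9; the TNF receptor superfamily median became −0.037 on day 1, and in myeloma against naive mice the exhaustion median became 0.097 and the NF-kB median −0.053. TMM scaling gave −0.043 for the latter. In non-naive cells only, 8 lists stood out in myeloma against naive mice, with exhaustion at 0.11, and 4 in control IgG day 18 against day 0, with terminal effector at −0.17, interferon gamma at −0.093, Isg15 at −0.30, Ifit3 at −0.077, Ly6c2 at −0.070, Cxcr3 at −0.030 and Ly6a at −0.00058. In the same cells anti-CD137 against control IgG gave on day 1 −0.31 for cytotoxic, −0.025 for TNF receptor superfamily, −0.19 for type I interferon, −0.17 for interferon gamma and −0.0023 for oxidative phosphorylation genes. It gave on day 11 −0.13 for terminal effector, −0.55 for type I interferon, −0.045 for tissue residency, −0.89 for NK-type receptor and −0.87 for NK cell genes, −1.04 for Isg15, −0.79 for Klrk1 and −0.37 for Ly6a, and on day 18 −0.20 for type I interferon, −0.46 for tissue residency and −0.21 for Isg15.

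In naive-marker-high cells only, 9 lists stood out on day 11 and 6 in control IgG day 18 against day 0, with terminal effector at −0.39 and tissue residency at −0.074. Anti-CD137 against control IgG gave 0.071 for erythroid genes on day 1. On day 11 it gave −0.0034 for TNF receptor superfamily, 0.29 for interleukin 2 and −0.099 for glycolysis genes, −0.049 for Lgals1, −0.017 for Bcl2a1b, 0.44 for Tnfsf8, −0.033 for Stmn1, −0.093 for Gapdh, −0.074 for Klrk1 and −0.36 for Igkc. On day 18 it gave 0.52 for interleukin 2, 0.12 for ribosomal protein and −0.48 for plasma cell genes, −0.028 for Havcr2, 0.23 for Tnfsf8 and −0.77 for Igkc.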

Other observations

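Both tests of cluster make-up and that of handling described here, and the comparisons within naive-marker-low cells, were chosen after the result was seen, and the libraries compared first have no test. Between days 11 and 18 of anti-CD137 treatment, genes of T cell exhaustion were higher and genes of short-lived effector cells lower. All 17 exhaustion genes were higher on day 18 (median log2 ratio 0.91), among them Havcr2 (1.61), Rgs16 (1.31) and Lag3 (1.10), and within naive-marker-low cells all 18 measured ones were (0.66), where the exhausted-like cluster held 184 of 3572 cells on day 11 and 1437 of 6057 on day 18. Of 14 terminal effector genes 12 were lower (−0.54), with S100a4 at −0.83 and Lgals1 at −0.68, and Gzma, a granzyme of effector cells, stood at 88.2 CPM against 231. Neutrophil genes were lower (−1.95, 4 of 4). Under control IgG, cytotoxic (0.72, 15 of 16) and exhaustion genes (0.59, 11 of 11) were higher on day 18 than on day 11. Memory-like cells were 512 of 5608 CD8 T-like control cells on day 11 and 758 of 5371 on day 18. The make-up by tier therefore enters these medians. In the 364 and 85 naive-marker-low cells of these control libraries, Pdcd1 stood at 239 CPM on day 18 against 72.0 on day 11. Tox stood at 327 against 81.4 there and Havcr2 at 134 against 21.9, while Cd160 was lower (99.6 against 122). Higher levels within this tier were thus not particular to anti-CD137. Among these control cells the exhausted-like cluster held 1 of 85 on day 11 and 30 of 364 on day 18. The cluster led by Ccl5 held 20 and 187 of them, and interferon-responding-like cells 54 and 128. The make-up by cluster therefore enters the control values as well, and they do not show a rise per cell. Both day 18 libraries stood apart from all others in Gm42418 (896 CPM with control IgG and 674 with anti-CD137, against 195 to 292) and Tnks2 (89.4 and 97.4, against 31.5 to 50.7), and Hist1h1e was higher in both (43.3 and 117, against 18.1 to 27.8), so these differences are mixed with a library difference of that day, whose cause was not tested.

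Anti-CD137 on day 4 has no control library in the table. A naive-like cluster led by the NF-kB genes Nfkbia, Relb, Bcl3 and Nfkb2 held 7.97% of its cells (7.28 to 8.70), against 3.92% with anti-CD137 on day 1 and 6.36% with control IgG on day 11. Interferon-responding-like cells held 11.4% of the naive-marker-high cells (10.6 to 12.3), against 8.13% on day 1. Immediate early genes were higher than with anti-CD137 on day 1 (median 1.26, 10 of 10). This list also differed by −0.55 between the control IgG library of day 1 and the untreated myeloma library, neither given the agonist. Differences between libraries are thus mixed with this change. In naive-marker-low cells of the control IgG library of day 18, 45.6% of 90 T cell receptor beta variable values came from Trbv1, found in 35 of 364 cells, whereas under anti-CD137 the leading gene was Trbv12-2 with 24.8% of 330 on day 11 and 22.3% of 1241 on day 18.

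Interferon gamma genes were higher in the naive-marker-high cells of anti-CD137 libraries than in those of controls on days 11 and 18 (medians 0.93, 17 of 19, and 1.08, 19 of 19), and the neutrophil gene S100a9 stood at 4.79 CPM in these cells on day 1 (against 0.156), 469 on day 11 (against 11.3) and 0 on day 18 (against 1.18). RNA of activated cells in the same droplets was argued against: the level added to these genes, as a share of their level in naive-marker-low cells, was 42.9 and 10.7 times the share for cytotoxic genes, where such RNA would give at most 1.5, although cells dominated by that RNA would have clustered elsewhere. Another make-up of these cells by cluster was argued against as the whole cause: with both arms given the control make-up over clusters with at least 10 cells in each, the median was 0.65 on day 11 (95% interval over cells 0.43 to 0.73, 17 of 19 higher) and 0.64 on day 18 (0.46 to 0.97, 19 of 19). As the larger part it cannot be told apart from a change within cells, since interferon-responding-like cells held 42.9% and 55.2% of these cells against 7.20% and 5.01%, and the median within clusters 0, 2 and 5 was 0.511 to 0.912 of that over all, from 94, 31 and 201 anti-CD137 cells on day 11 and only 10, 42 and 20 on day 18, in a test changed after averages over 4 clusters (0.671 on day 11, none on day 18) and 3 clusters (0.746 and 0.825) had come out above the bound set against it. Isg15 and Ifit3 of the type I interferon list were higher in these cells too. Isg15 stood at 83.9 and 136 CPM against 34.5 and 36.1, and Ifit3 at 50.7 and 66.1 against 17.9 and 27.6. Exposure of naive cells to interferon gamma from activated neighbours may account for the rest, but these values do not tell it apart from type I interferon. Neither was tested, nor was RNA of neutrophils in the droplets of day 11.

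Igkc was found in 52.2% and 53.5% of cells of the anti-CD137 libraries of days 11 and 18, against 1.16% and 3.05% of control cells (median depth-equalised totals of 3827 and 3343, and 3627 and 3629). Free RNA from antibody-secreting cells was argued against, since naive-marker-low cells held 41.2 and 17.6 times the CPM of naive-marker-high cells in the same library, where free RNA would give at most 2. B cells or plasma cells in the same droplets were argued against, since the 1% of cells with the most Igkc held 7.64% and 7.21% of it, and the plasma cell gene Jchain stood at 0.298 and 0.512 CPM in naive-marker-low cells. Within naive-marker-low cells Igkc was found in 65.5% and 57.2% of anti-CD137 cells, against 5.88% and 12.4% of control cells. Memory-like cells stood at 255 and 186 CPM against 8.20 and 9.51, and naive-marker-high cells at 9.28 and 18.5 against 14.8 and 38.8. The make-up by tier alone therefore does not account for the difference. Transcription of the kappa locus by activated T cells may contribute, though few activated control cells held Igkc. This was not tested, and reads shared with other genes or RNA taken up from other cells stay open.

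Immediate early genes were lower with anti-CD137 on day 1 (median −0.44, 9 of 10). They also differed by −0.55 between the control IgG library of day 1 and the untreated myeloma library, neither of which met the agonist, so a difference in handling between libraries may account for it. An effect of the agonist stays open, as 1 library per group leaves handling and treatment confounded.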
